A study of Mus musculus with 16 samples.

How the data were processed

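Stromal cells positive for PDGFRb were sorted by flow cytometry from inguinal white adipose tissue of C57BL/6 mice and divided into DPP4_neg and DPP4_pos adipose progenitors (APCs), per the labels. They were grown in medium with 10% serum and given PBS vehicle or isoproterenol, an agonist of beta-adrenergic receptors, for 4 h. The labels give the dose as 10 mM, far above the micromolar doses usual for cultured cells, and an error of unit in the label cannot be ruled out. Each of the 16 libraries was made from 500 ng of total RNA, and each of the 4 groups has 4 libraries. The kit named in the labels does not say whether strand was kept, so reads of a gene and of an overlapping or antisense partner cannot be separated.

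The submitters' processing notes name Trim Galore 0.4.1, HISAT2 2.0.1, featureCounts 1.4.6 and DESeq2 1.6.3, with the builds GRCm38 and mm10. Their order, settings and gene annotation are not given in the sources used here. The deposited table holds a normalized signal per gene and library, the read count divided by a size factor, as its header and its values show. In each library the values were whole multiples of a fixed step. Dividing by that step gave whole reads for 100.0% of the 280334 values above 0, within 0.001 of a whole number. The reads in genes obtained in this way ranged from 9823799 to 28627223 per library. They came to 16479650 to 28627223 in DPP4_neg vehicle, 10191846 to 22121496 in DPP4_neg isoproterenol, 17189166 to 20425332 in DPP4_pos vehicle and 9823799 to 16563940 in DPP4_pos isoproterenol libraries.

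The table has 27179 entries. Of these, 4224 were at 0 in all libraries, and 958 carried no symbol, with 0.093% of the normalized counts. Entries without a symbol went through the same filter as the others and are not named. A spreadsheet had turned 26 symbols into dates, and all 26 were restored through their Entrez identifiers. Of the identifiers, 25275 matched the RefSeq table of GRCm38.p6, from which gene positions were taken. Genes were tested when their normalized count was at least 10 in at least 4 libraries, which left 14005. Genes whose reads a near-identical copy could share, such as Ifit3, are not named. The mitochondrial genes COX2, COX3 and ATP6 had means of 56.9, 14.4 and 11.7 normalized counts where COX1 had 103100, so mitochondrial shares hold few reads of these 3 genes.

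The main test was limma with a mean-variance trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), with all 16 libraries in a fit of 4 group means and Benjamini-Hochberg adjustment. An adjusted p under 0.05 counted as a change. Fold changes are on this log2 scale, which understates the change of low genes, and are given ± the standard error. The comparisons were isoproterenol against vehicle in each population, the difference between these responses, and DPP4_pos against DPP4_neg APCs under each treatment. Where a group had 10 reads or fewer in a gene, the fold is a ratio of reads with a 95% counting interval, or, against a group at 0, a lower bound from a floor of 3 counts over the group. Such intervals and floors cover counting error only. Means of normalized counts are given ± SD with 4 libraries per group.

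Gene lists, 38 of them with 867 members written and 860 found in the table, were compiled from textbook knowledge, not from these libraries. The 35 with at least 5 measured members were tested in each of the 5 comparisons with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 175 tests, with an estimated correlation beside it. A member counts as risen or fallen at the threshold over all genes tested. Sums over a list hold all its members found in the table, also those that were not tested. The lists cover the cAMP and CREB early response, adrenergic receptors and cAMP signalling, cytokines and chemokines, markers of DPP4+ interstitial progenitors, committed preadipocytes and CD142+ progenitors, PDGFRb+ stromal identity, adipocyte differentiation, thermogenic genes, lipolysis, extracellular matrix, matrix proteases, YAP and SRF targets, NF-kB targets, interferon-stimulated genes, IL-6 family and JAK-STAT feedback, cell cycle, Wnt, BMP, circadian clock, NRF2, metallothioneins, HIF targets, ER stress and the integrated stress response, heat shock, p53 targets, glucocorticoid targets, sterol synthesis, growth factors, mitochondrially encoded genes and ribosomal proteins. ER stress and the integrated stress response form a single mixed list, in places named only by its second part. The others hold markers of macrophages and leukocytes, endothelial, mural, mesothelial, epithelial, Schwann and skeletal muscle cells.

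Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Among the genes the rule named in advance were Dpp4, Pdgfrb, Pdgfra, Adrb1, Adrb3, Il33, Ccl2, Pparg, Fabp4, Ucp1, Ppargc1a and Nr4a1. The rule added, among changed genes with a mean normalized count of at least 50 and with groups that did not overlap, the 10 highest and 10 lowest fold changes of each treatment and of the vehicle comparison. The difference of responses gave 8 and 8, without the requirement on overlap, and the comparison under isoproterenol 5 and 5. Described lists gave up to 4 members by adjusted p. Unnamed gene models were passed over, and part of the genes so chosen, in advance or by their values, are not reported here.

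The test was checked on simulated data, reads drawn for the real genes with 50 genes changed at each fold. All groups had the DPP4_neg vehicle means, and the spread between replicates was set, not estimated from these libraries. Far fewer genes changed than were called here, so the rates that follow describe the simulation and not these data. For the response of DPP4_neg APCs the test recovered 92% of genes raised by 0.585 on the log2 scale, 100% of those raised by 1 and 98% of those lowered by 1, with false calls at 0.0599% of the unchanged genes. The response of DPP4_pos APCs gave 96%, 100%, 96% and 0.12%, and the difference of responses 80%, 96%, 90% and 0.09%. The comparison of populations under vehicle gave 92%, 100%, 100% and 0.0375%, and that under isoproterenol 92%, 98%, 96% and 0.15%.

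Alternatives were libraries left out singly, another pseudocount, another filter, quantile normalization, the same total in every library, robust variances, fits to the compared groups alone, a replicate block, a 2-fold minimum, an estimated correlation, and count models on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. Figures and summary tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.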

Results

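The transcriptomes of cultured PDGFRb+ progenitors from mouse inguinal white fat were measured by RNA sequencing in 16 libraries, 4 each of DPP4_neg and DPP4_pos APCs given vehicle or isoproterenol for 4 h. Isoproterenol is a synthetic agonist of beta-adrenergic receptors and stands in for the sympathetic signal that cold sends to fat. DPP4 is a surface peptidase carried by interstitial progenitors of subcutaneous fat. Reads in genes ranged from 9823799 to 28627223 per library. Dpp4, on chromosome 2 from 62330073 to 62412315 in GRCm38, followed the sort, with 21.1 ± 4.16 normalized counts in DPP4_neg vehicle and 3053 ± 186 in DPP4_pos vehicle libraries (mean ± SD, n = 4). The first 2 principal components held 54.4% and 31.1% of the variance and separated the 4 groups. Pairs of libraries within a group correlated across genes at r = 0.986 to 0.995, and each pair differed by more than counting noise, with a chi-square per degree of freedom of 1.618 to 9.387. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

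**Figure D1:**
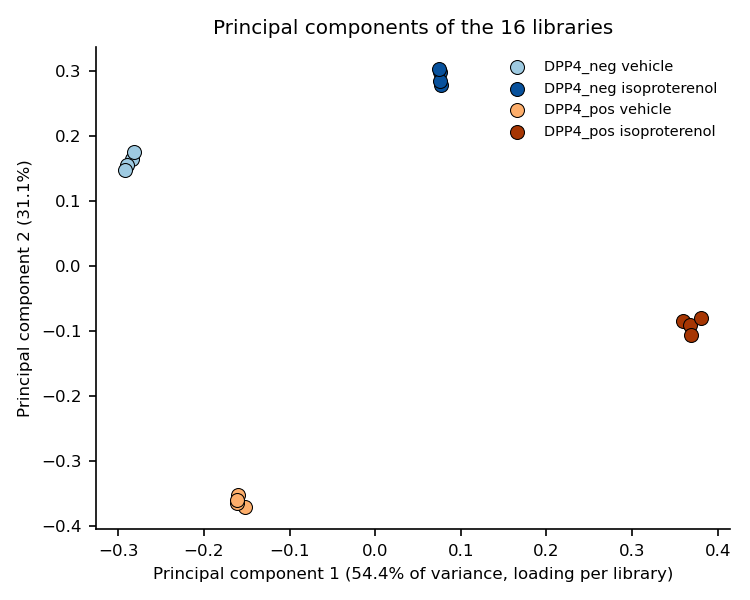
Principal components of log2(normalized count + 1), 1 point per library, with the share of variance on each axis. The 4 groups form separate clusters, with 54.4% of the variance on the first component and 31.1% on the second.

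How the populations differ before stimulation was asked of the vehicle libraries, DPP4_pos against DPP4_neg. DPP4_pos APCs had higher levels of interstitial progenitor markers, matrix proteases, interferon-stimulated genes and sterol synthesis genes, and lower levels of contractile and adipocyte genes. Of these list calls, those of interferon-stimulated genes (adjusted p = 0.32), sterol synthesis (adjusted p = 0.0648) and adipocyte genes (adjusted p = 0.262) were lost with an estimated correlation, and the others held. Besides Dpp4 itself, 140-fold higher and used in the sort, they had 53.5-fold more Il33 (1893 ± 137 against 34.4 ± 2.73 normalized counts), the alarmin cytokine encoded on chromosome 19 from 29925113 to 29960718. The angiotensin-converting enzyme gene Ace was 104-fold higher, Clec3b (tetranectin) 92.3-fold and the surface sialomucin gene Cd34 71-fold (log2 difference 6.15 ± 0.11). Aldh1a2, an enzyme of retinoic acid synthesis, was 128-fold lower in DPP4_pos APCs, the chemokine gene Cxcl14 38.2-fold, the receptor tyrosine kinase gene Ret 37.6-fold and the LIM-domain gene Lmcd1 34.3-fold lower. Bmp7, which encodes a growth factor that promotes brown fat formation, had no read in DPP4_neg vehicle libraries and was at least 168-fold higher in DPP4_pos.

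Of 25 measured DPP4+ interstitial progenitor markers, 24 were higher in DPP4_pos APCs and 1 was lower. Adjusted over the list alone, all 25 passed. The list includes Dpp4, and its median log2 difference was 1.4 (camera adjusted p = 1.55e-11, and adjusted p = 0.000505 with an estimated correlation). Examples were Pi16, a peptidase inhibitor, at 5.81 ± 0.11, the procollagen enhancer Pcolce2 at 2.36 ± 0.05 and the interleukin receptor subunit Il13ra1 at 1.95 ± 0.04. Among 21 matrix proteases and inhibitors, 17 were higher and 4 lower, 21 adjusted over the list alone, including stromelysin Mmp3 (6.03 ± 0.09), gelatinase Mmp2 (3.52 ± 0.03) and Serpine2 (2.01 ± 0.04). The protease call held with an estimated correlation (adjusted p = 0.0311). NF-kB targets were higher in 16 of 22 and lower in 4, 20 adjusted over the list alone, with the acute-phase gene Saa3 at 6.38 ± 0.11 (camera adjusted p = 0.0012, and adjusted p = 0.0311 with an estimated correlation). Sterol synthesis genes were higher in 19 of 20, 19 adjusted over the list alone, with Insig1 at 0.81 ± 0.03 and Cyp51 at 0.93 ± 0.04. The sterol call had adjusted p = 5.6e-10 with camera and adjusted p = 0.0648 with an estimated correlation. Of the chemokine genes, Ccl8 was 47.1-fold higher, while Ccl2, which recruits monocytes, did not pass (−0.15 ± 0.10, limma adjusted p = 0.194), though it did without DPP4_pos vehicle replicate 1 (−0.26).

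All 25 measured interferon-stimulated genes were higher in DPP4_pos vehicle libraries, 25 also adjusted over the list alone, with a median log2 difference of 3.85. The 2'-5' oligoadenylate synthetase genes Oas2 and Oasl1 were higher by 6.35 ± 0.48 and 4.71 ± 0.34, Ifit1 by 5.63 ± 0.44, and the regulators Irf7 and Stat2 by 5.08 ± 0.39 and 2.41 ± 0.20. The camera call (adjusted p = 7.78e-09) was lost with an estimated correlation (adjusted p = 0.32 with an estimated correlation). The list summed to 30190 ± 11700 normalized counts in DPP4_pos vehicle libraries, from 18200 to 46020 per library, and to 5849 ± 405 in DPP4_neg vehicle. Macrophage and leukocyte markers summed to 934.2 ± 405 and 747.9 ± 304 in the same groups. Both sums were highest in the same DPP4_pos vehicle library, replicate 1, at 46020 and 1536. Endothelial markers were higher in 7 of 10 and lower in 1, 8 adjusted over the list alone, with a median of 1.2 (camera adjusted p = 0.0518). They summed to 2535 ± 54.2 in DPP4_pos and 2587 ± 81.6 in DPP4_neg vehicle libraries. Schwann cell markers were higher in 4 of 6 and lower in 2, 6 adjusted over the list alone (camera adjusted p = 0.192). They summed to 5235 ± 177 and 1082 ± 109.

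Contractile genes were lower in DPP4_pos APCs. Of 26 YAP, SRF and cytoskeleton targets, 24 were lower and 2 higher, 26 adjusted over the list alone, with a median of −1.84 (camera adjusted p = 2.12e-13, and adjusted p = 0.0385 with an estimated correlation). Smooth muscle actin Acta2 stood at 99430 ± 4490 normalized counts in DPP4_neg and 6126 ± 484 in DPP4_pos vehicle libraries, and Myl9, Tagln and Tpm1 differed by −3.49 ± 0.05, −3.48 ± 0.05 and −2.51 ± 0.04. Markers of mural cells, the smooth muscle cells and pericytes of vessel walls, were lower in 10 of 14, higher in 1 and not called in 3, 11 adjusted over the list alone (camera adjusted p = 0.00022, and adjusted p = 0.0206 with an estimated correlation). Myh11 (−4.82 ± 0.13), Cnn1 (−4.30 ± 0.10) and the channel subunit Abcc9 (−2.62 ± 0.06) were among them. The mural list, which holds Acta2, summed to 114600 ± 5070 normalized counts in DPP4_neg and 8606 ± 495 in DPP4_pos vehicle libraries.

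**Figure D2:**
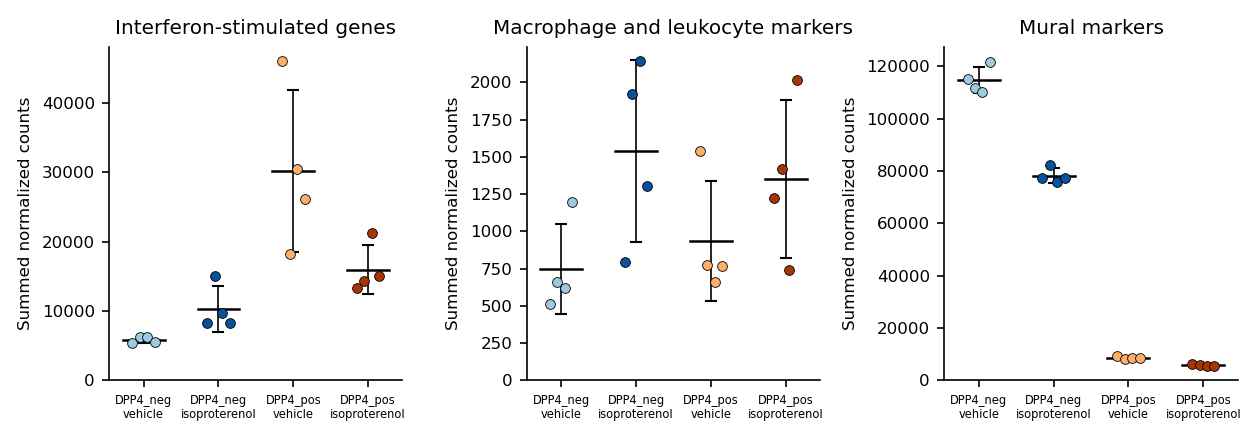
Summed normalized counts (linear axis) of interferon-stimulated genes, macrophage and leukocyte markers and mural markers in each group, with points for libraries, a line for the mean and bars for the SD (n = 4). The interferon-stimulated sum is 30190 in DPP4_pos vehicle against 5849 in DPP4_neg vehicle, and the mural sum 8606 against 114600.

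Adipocyte genes were lower in 17 of 28, higher in 7 and not called in 4, 24 adjusted over the list alone. Perilipin Plin4 (−2.29 ± 0.07), adipsin Cfd (−2.16 ± 0.07), the desaturase Scd1 (−1.82 ± 0.06), Adipoq (−1.48 ± 0.05), the fatty acid binding protein Fabp4 (−1.55 ± 0.08) and the adipogenic receptor Pparg (−0.86 ± 0.05) were lower. The camera call (adjusted p = 0.00978) was lost with an estimated correlation (adjusted p = 0.262 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 40 of 40 by a median of 0.42 on the log2 scale, with adjusted p = 1.64e-11 and adjusted p = 0.254 with an estimated correlation. Genes of ER stress and the integrated stress response were lower in 20 of 21, 20 adjusted over the list alone (camera adjusted p = 1.34e-08, and adjusted p = 0.0648 with an estimated correlation). HIF targets were lower in 18 of 25 and higher in 6, 24 adjusted over the list alone, with a median of −0.78 (camera adjusted p = 0.000381, and adjusted p = 0.0648 with an estimated correlation). The receptor genes Adrb3 and Adrb1 were lower in DPP4_pos APCs by log2 differences of −1.35 ± 0.13 and −1.06 ± 0.31, and the alpha-adrenergic receptor gene Adra2a by −5.07 ± 0.23. Pdgfra was 2.51-fold higher (1.33 ± 0.04) and Pdgfrb lower (−0.58 ± 0.05), while Ucp1 had 5 reads in each vehicle group. Nr4a1, an orphan nuclear receptor gene of the early response, was lower by −1.42 ± 0.11. Ppargc1a, a coactivator of mitochondrial biogenesis, was lower by −0.39 ± 0.13 (limma adjusted p = 0.0123), a call that ended without DPP4_pos vehicle replicate 1 (−0.29). Limma called 9326 of 14005 genes, 4428 higher and 4898 lower, of which 2216 differed at least 2-fold, and the groups did not overlap in 67.3% of genes where chance gives 2.86%.

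In DPP4_neg APCs isoproterenol raised cAMP-responsive genes, several cytokine genes and NRF2 targets and lowered cytoskeletal and adipocyte genes and the receptor gene Adrb3. Of these list calls, that of the cAMP response held with an estimated correlation, and those of cytokines (adjusted p = 0.131), NRF2 targets (adjusted p = 0.132), cytoskeletal genes (adjusted p = 0.0701) and adipocyte genes (adjusted p = 0.0531) did not. Il33 rose 53.6-fold, from 34.4 ± 2.73 to 1897 ± 90.3 normalized counts, and the cytokine gene Il11 rose 166-fold. Dio2, the deiodinase that makes active thyroid hormone in brown fat, rose 201-fold (log2 change 7.65 ± 0.16). The renin gene Ren1 had no read in vehicle libraries and rose at least 738-fold, and Ramp3, a partner of calcitonin-family receptors, rose from 5 reads, a ratio of 1130 (486 to 3500). Connective tissue growth factor Ctgf fell 102-fold, from 32530 ± 1090 to 319.4 ± 41.2 normalized counts. Adrb3, the main beta-adrenergic receptor of mouse fat, fell 27.9-fold, from 1969 ± 138 to 70.5 ± 14.7.

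Of 31 genes of the cAMP and CREB early response, 27 rose and 4 fell, 31 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 1.64e-11, and adjusted p = 0.00769 with an estimated correlation). Crem, an inducible repressor of cAMP-responsive genes, rose by 4.62 ± 0.06, the GTPase gene Gem by 5.59 ± 0.08, the phosphodiesterases Pde4d and Pde10a by 3.70 ± 0.06 and 3.95 ± 0.07, and the nuclear receptor Nr4a1 by 4.47 ± 0.11. Cytokine and chemokine genes rose in 15 of 28, fell in 6 and did not pass in 7, 21 adjusted over the list alone, with Cxcl14 at 2.19 ± 0.06 and Cxcl1 at 2.83 ± 0.11. The camera call (adjusted p = 0.0127) was lost with an estimated correlation (adjusted p = 0.131 with an estimated correlation). Ccl2 fell by 0.68 on the log2 scale, from 872.1 ± 102 to 544.1 ± 49.9 normalized counts. NRF2 targets rose in 17 of 22 and fell in 2, 19 adjusted over the list alone, among them the cystine transporter Slc7a11 (3.32 ± 0.07), sulfiredoxin Srxn1 (3.84 ± 0.04) and Nqo1 (2.37 ± 0.06), with camera adjusted p = 1.99e-08 and adjusted p = 0.132 with an estimated correlation. Metallothionein and metal response genes rose in 7 of 9 and fell in 1, 8 adjusted over the list alone (camera adjusted p = 0.0067, and adjusted p = 0.0648 with an estimated correlation). NF-kB targets rose in 12 of 22 and fell in 7, 19 adjusted over the list alone, and IL-6 family and JAK-STAT feedback genes rose in 10 of 19 and fell in 5, 15 adjusted over the list alone. Both had camera adjusted p = 0.0475, with adjusted p = 0.132 and adjusted p = 0.129 with an estimated correlation, and the latter adjusted p = 0.0629 under quantile normalization. With the replicate block camera gave adjusted p = 0.0568 for NF-kB targets and adjusted p = 0.0518 for IL-6 family genes. Ribosomal protein genes rose in 38 of 40 by a median of 0.26 (camera adjusted p = 1.4e-08, and adjusted p = 0.32 with an estimated correlation).

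YAP, SRF and cytoskeleton targets fell in 24 of 26 and rose in 2, 26 adjusted over the list alone, with a median of −1.04 (camera adjusted p = 1.19e-09, and adjusted p = 0.0701 with an estimated correlation). Mural markers fell in 8 of 14 and rose in 2, 11 adjusted over the list alone (camera adjusted p = 0.0991), and their sum went from 114600 ± 5070 to 78080 ± 2860 normalized counts. Besides Ctgf, the focal adhesion gene Vcl fell by 2.47 on the log2 scale, Cyr61 by 3.03, Ankrd1 by 4.73 and Fhl2 by 4.42. The vasodilator peptide gene Adm fell 42-fold and osteoprotegerin Tnfrsf11b 50.2-fold. Adipocyte genes fell in 23 of 28 and rose in 5, 28 adjusted over the list alone (camera adjusted p = 1.24e-06, and adjusted p = 0.0531 with an estimated correlation). Plin4 changed by −2.81 ± 0.07, Plin1 by −2.53 ± 0.07, Fabp4 by −1.16 ± 0.08 and Pparg by −0.50 ± 0.05, whereas Dgat1, which makes triglyceride, rose by 3.53 ± 0.05. Thermogenic genes were not called as a list, with 9 of 21 up, 9 down and 3 not passed, 18 adjusted over the list alone (camera adjusted p = 0.595). Within the list the uncoupling protein gene Ucp1 went from 5 reads to 684, a ratio of 192 (81.8 to 593), and Ppargc1a rose 2.2-fold.

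In the list of adrenergic receptors and cAMP signalling, 9 of 31 rose, 16 fell and 6 did not pass, 25 adjusted over the list alone (camera adjusted p = 0.227). The adenylyl cyclase gene Adcy3 rose by 1.70 on the log2 scale, while Adrb1 did not pass (0.20 ± 0.31, limma adjusted p = 0.593). The DPP4+ progenitor markers rose in 13 of 25 and fell in 10, 23 adjusted over the list alone (camera adjusted p = 0.446). Pi16 rose 119-fold, the complement regulator Cd55 46.3-fold and the chemokine receptor Ackr3 by 3.14 ± 0.08, while Dpp4 itself fell, from 21.1 ± 4.16 to 9.89 ± 2.29 normalized counts. Pdgfra and Pdgfrb each changed by −0.33, with standard errors of 0.04 and 0.05. Interferon-stimulated genes rose in 8 of 25, fell in 5 and did not pass in 12, 11 adjusted over the list alone (camera adjusted p = 0.774). They summed to 10300 ± 3270 normalized counts under isoproterenol and 5849 ± 405 under vehicle. The lowest isoproterenol library (8197) was above the highest vehicle library (6206). Their sum was highest in DPP4_neg isoproterenol replicate 2, at 15100 where the others of its group reached 9643 at most. Macrophage and leukocyte markers, 3 of 15 of which rose, summed to 1540 ± 611 normalized counts under isoproterenol and 747.9 ± 304 under vehicle. Limma called 9199 genes, 4496 up and 4703 down, 2137 of them at least 2-fold, and 58.9% of genes had groups that did not overlap.

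In DPP4_pos APCs isoproterenol raised cytokine, NF-kB, hypoxia, NRF2 and stress response genes along with the cAMP response, and lowered both PDGF receptors, interferon-stimulated genes and adipocyte genes. Of these list calls, those of the cAMP response and NF-kB targets held with an estimated correlation, and those of cytokines (adjusted p = 0.134), hypoxia genes (adjusted p = 0.0531), NRF2 targets (adjusted p = 0.231), the integrated stress response (adjusted p = 0.201), heat shock (adjusted p = 0.249), interferon-stimulated genes (adjusted p = 0.673) and adipocyte genes (adjusted p = 0.122) did not. Il33 rose 34.4-fold, from 1893 ± 137 to 64970 ± 1450 normalized counts. Il11 rose 689-fold and Il6 50.1-fold, to 12280 ± 1210 and 3012 ± 349. Dio2 rose 802-fold and the hyaluronan synthase gene Has1 359-fold. Pdgfra fell 3.15-fold, from 33550 ± 239 to 10640 ± 438, and Pdgfrb 3.6-fold, from 7562 ± 367 to 2105 ± 163, while Adrb3 fell 47.6-fold, from 773.9 ± 52.2 to 15.5 ± 3.23.

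**Figure D3:**
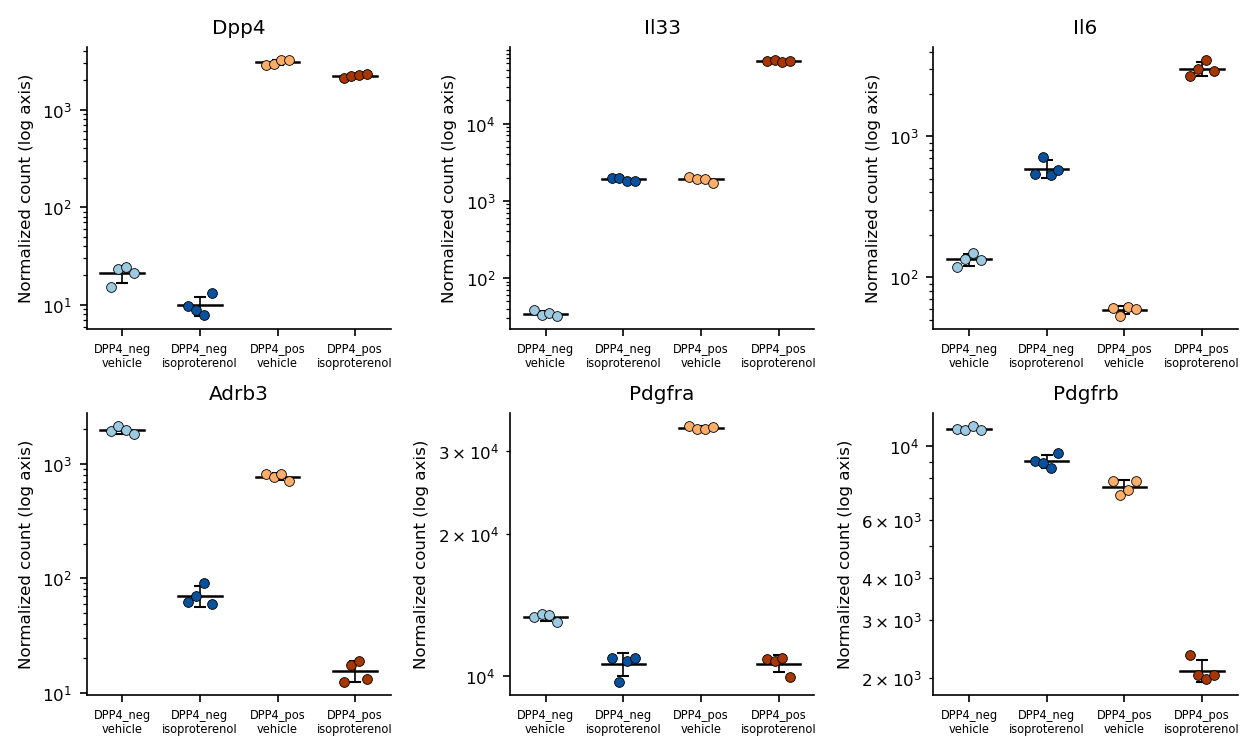
Normalized counts (log axis) of Dpp4, Il33, Il6, Adrb3, Pdgfra and Pdgfrb in each library, with a line for the group mean and bars for the SD (n = 4). Il33 reaches 64970 in DPP4_pos isoproterenol libraries against 1897 in DPP4_neg isoproterenol libraries.

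The cAMP and CREB early response rose in 27 of 31 and fell in 3, 30 adjusted over the list alone, with a median of 2.45 (camera adjusted p = 5.19e-10, and adjusted p = 0.0125 with an estimated correlation). Crem rose by 5.42 ± 0.06, Pde4d by 5.57 ± 0.06, the salt-inducible kinase gene Sik1 by 3.97 ± 0.05 and Nr4a1 by 6.89 ± 0.11. Among cytokines and chemokines 17 of 28 rose, 8 fell and 3 did not pass, 25 adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.134 with an estimated correlation). Lif, of the IL-6 family, rose by 4.44 ± 0.06, the neutrophil attractant Cxcl1 by 5.84 ± 0.11 and Ccl2 by 0.84 ± 0.10, and Cxcl2 went from 2 reads to 1204, a ratio of 1070 (296 to 8860). NF-kB targets rose in 16 of 22 and fell in 1, 17 adjusted over the list alone, including Sod2 (2.56 ± 0.04), and IL-6 family and JAK-STAT feedback genes rose in 13 of 19 and fell in 3, 16 adjusted over the list alone, including Socs3 (2.54 ± 0.05). Their camera calls (adjusted p = 0.000917 and 0.0011) each kept adjusted p = 0.0311 with an estimated correlation. The lactate receptor gene Hcar1 went down to 5 reads from 284, a ratio of 31.9 (13.5 to 99). Wdr86 and the guanylate cyclase gene Gucy1a1 fell 55-fold and 30.2-fold. Ren1, Ramp3 and Sptssb, which encodes a subunit of serine palmitoyltransferase, rose from 5, 9 and 4 reads by ratios of 1460 (624 to 4490), 892 (469 to 1950) and 4150 (1620 to 15200), Tox3 at least 474-fold from no read, and the keratin gene Krt20 282-fold.

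Stress-related groups rose as well. NRF2 targets rose in 18 of 22 and fell in 2, 20 adjusted over the list alone, with Slc7a11 169-fold higher (7.40 ± 0.07), Srxn1 at 4.92 ± 0.04 and thioredoxin reductase Txnrd1 at 3.30 ± 0.03 (camera adjusted p = 9.03e-06, and adjusted p = 0.231 with an estimated correlation). HIF targets rose in 19 of 25 and fell in 4, 23 adjusted over the list alone, led by hexokinase Hk2 (4.33 ± 0.06), Ddit4 (4.07 ± 0.07) and the glucose transporter Slc2a1 (2.82 ± 0.05), with camera adjusted p = 0.000124 and adjusted p = 0.0531 with an estimated correlation. Metallothionein and metal response genes rose in 8 of 9 and fell in 1, 9 adjusted over the list alone, including Mt1 (2.69 ± 0.05) and Mt2 (3.30 ± 0.07), and the call held (adjusted p = 0.0421 with an estimated correlation). Genes of ER stress and the integrated stress response rose in 17 of 21 and fell in 4, 21 adjusted over the list alone, such as the chaperone Hspa5 (1.57 ± 0.04) and Atf4 (1.38 ± 0.03), with camera adjusted p = 0.000142 and adjusted p = 0.201 with an estimated correlation. Heat shock genes rose in 10 of 13 and fell in 2, 12 adjusted over the list alone, including Hsph1 (3.80 ± 0.04) and the cochaperone Bag3 (2.39 ± 0.05), with camera adjusted p = 0.00132 and adjusted p = 0.249 with an estimated correlation. All 40 ribosomal protein genes rose, by a median of 0.46 (camera adjusted p = 1.4e-08, and adjusted p = 0.32 with an estimated correlation), but under quantile normalization 11 rose, 7 fell and the median was 0.03.

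Interferon-stimulated genes fell in 21 of 25 and rose in 2, 23 adjusted over the list alone, with a median of −1.69. Ifit2 changed by −4.69 ± 0.27 and the GTPase gene Gbp2 by −2.81 ± 0.19. The camera call (adjusted p = 0.015) was lost with an estimated correlation (adjusted p = 0.673 with an estimated correlation) and with the same total per library (adjusted p = 0.112), and the sum went from 30190 ± 11700 to 15970 ± 3570 normalized counts while macrophage and leukocyte markers summed to 934.2 ± 405 and 1350 ± 530. Adipocyte genes fell in 24 of 28 and rose in 4, 28 adjusted over the list alone (camera adjusted p = 0.000139, and adjusted p = 0.122 with an estimated correlation), including Plin4 (−2.82 ± 0.07), Plin1 (−2.59 ± 0.07), Fabp4 (−1.29 ± 0.08) and Pparg (−1.23 ± 0.05), with Dgat1 up by 3.71 ± 0.05. YAP, SRF and cytoskeleton targets fell in 21 of 26 and rose in 5, 26 adjusted over the list alone, with Ctgf 41.5-fold lower and Vcl at −2.15 ± 0.04 (camera adjusted p = 0.00185, and adjusted p = 0.32 with an estimated correlation). Thermogenic genes rose in 6 of 21, fell in 10 and did not pass in 5, 16 adjusted over the list alone (camera adjusted p = 0.707, median −0.54 and mean 0.13), with 8 up, 8 down and a median of −0.02 under quantile normalization. Ucp1 went from 5 reads to 202, a ratio of 72 (30.3 to 224), and Ppargc1a did not pass (0.21 ± 0.13, limma adjusted p = 0.145), passing under quantile normalization (0.74) and turning to −0.06 with the same total per library.

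The markers of DPP4+ progenitors rose in 11 of 25, fell in 10 and did not pass in 4, 21 adjusted over the list alone (camera adjusted p = 0.549, with a median of −0.05 that was 0.03 under quantile normalization). Dpp4 fell by 0.46 on the log2 scale, while Cd55 rose by 5.99 ± 0.05 and Pi16 by 5.39 ± 0.11. PDGFRb+ stromal identity genes rose in 4 of 18, fell in 11 and did not pass in 3, 15 adjusted over the list alone (camera adjusted p = 0.114, median −0.43). Under quantile normalization that list was called (adjusted p = 0.00293), with 2 up, 15 down and a median of −0.66. Adrenergic receptor and cAMP signalling genes rose in 12 of 31, fell in 15 and did not pass in 4, 27 adjusted over the list alone (camera adjusted p = 0.598), with Adrb1 not called at 0.31 ± 0.31, though called under quantile normalization at 0.78. Limma called 11581 genes, 5517 up and 6064 down, 4295 of them at least 2-fold (1607 up and 2688 down), and 77.8% of genes had groups that did not overlap. With the same total in every library the median of all genes went from −0.05 to −0.32, the calls were 3865 up and 7835 down, and those of at least 2-fold were 1164 up and 3554 down.

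Whether DPP4_pos APCs respond differently from DPP4_neg APCs was tested as the difference of the log2 responses, DPP4_pos minus DPP4_neg. The responses ran in parallel for most genes called in both, but the lists of IL-6 family, NF-kB, hypoxia and metal response genes differed upward in DPP4_pos APCs and both PDGF receptors fell further there. The IL-6 family and NF-kB lists share members, so their calls are not independent. Cytokines and chemokines as a list were not called. Across 14005 genes, which are not independent replicates, the responses correlated at Pearson r = 0.756 and Spearman rho = 0.725. Both populations called 3632 genes up, where independent lists would share 1771.113, and 3697 down, where they would share 2036.344. Of 8221 genes called in both, 892 moved in opposite directions. At 2-fold or more, 631 rose and 973 fell in both, with 100.746 and 241.642 from independent lists, and 26 rose in DPP4_neg and fell in DPP4_pos APCs while 10 did the reverse.

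**Figure D4:**
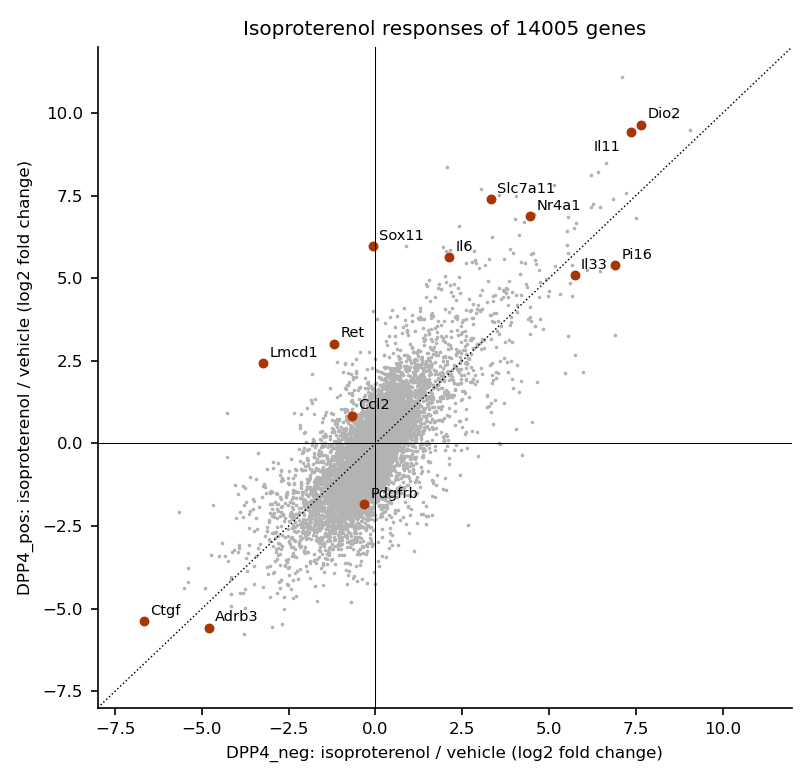
Log2 fold changes with isoproterenol in DPP4_neg APCs (horizontal) and DPP4_pos APCs (vertical), 1 point per tested gene, with named genes labelled and a dotted line at equality. Across 14005 genes the Pearson correlation is 0.756.

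The neural transcription factor gene Sox11 had a difference of 6.04 ± 0.13, with 246.4 and 235 normalized counts in DPP4_neg vehicle and isoproterenol libraries and 26.9 and 1730 in DPP4_pos ones. Lmcd1 (5.66 ± 0.17) and Ret (4.20 ± 0.11) fell in DPP4_neg and rose in DPP4_pos APCs, and Slc7a11 rose further in DPP4_pos APCs (4.09 ± 0.10). Il6 (3.52 ± 0.13), Lif (2.99 ± 0.09), the prostaglandin synthase gene Ptgs2 (3.79 ± 0.18) and Nr4a1 (2.42 ± 0.15) also differed upward. Ccl2 fell in DPP4_neg and rose in DPP4_pos APCs, a difference of 1.52 ± 0.14. Il33 rose less on the log2 scale in DPP4_pos APCs (−0.64 ± 0.08) from its higher vehicle level. Pdgfra (−1.32 ± 0.05), Pdgfrb (−1.52 ± 0.07), Pparg (−0.72 ± 0.08), Ppargc1a (−0.93 ± 0.18) and Adrb3 (−0.77 ± 0.18) differed downward, as did the phosphodiesterase gene Pde11a (−3.91 ± 0.30) and the actin-severing gene Scin (−3.61 ± 0.21). Dpp4 differed by 0.56 ± 0.18 (limma adjusted p = 0.0102), a call that ended under quantile normalization (0.10), the same total per library (0.30), a pseudocount of 8 (0.24), reads thinned to the shallowest library (0.55) and without the 3 libraries highest in macrophage markers (0.45). Fabp4 did not differ by this test (−0.13 ± 0.11, adjusted p = 0.308), but did under quantile normalization (−0.49) and with the same total per library (−0.39).

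Among the lists, IL-6 family and JAK-STAT feedback genes differed upward in 15 of 19 and downward in 2, 17 adjusted over the list alone, with Socs3 at 1.55 ± 0.07 (camera adjusted p = 7.83e-06, and adjusted p = 0.00649 with an estimated correlation). The cAMP response differed upward in 25 of 31 and downward in 5, 31 adjusted over the list alone, with Ier3 at 2.63 ± 0.09 and Sik1 at 1.86 ± 0.08, NF-kB targets in 14 of 22 and 3, 17 adjusted over the list alone, HIF targets in 18 of 25 and 5, 23 adjusted over the list alone, with Hk2 at 2.75 ± 0.08 and Slc2a1 at 2.10 ± 0.07, and metal response genes in 6 of 9 and 0, 6 adjusted over the list alone, with Mt1 at 1.79 ± 0.07 and Mt2 at 2.35 ± 0.10. These 4 calls held, with adjusted p = 0.0311, 0.0311, 0.0421 and 0.0485 with an estimated correlation. Some members are in more than 1 list. Il6, Bcl3, Lcn2 and Saa3 are in both the IL-6 family and NF-kB lists. Junb and Cebpd are in both the IL-6 family and cAMP lists, and Ptgs2 in both the NF-kB and cAMP lists. The IL-6 family, NF-kB and cAMP calls are therefore not independent. Cytokines and chemokines differed upward in 12 of 28 and downward in 10, 22 adjusted over the list alone, with a median of −0.16 and a mean of 0.77 (camera adjusted p = 0.267, and adjusted p = 0.462 with an estimated correlation). They were called upward with the same total per library (adjusted p = 0.0349), where the median was −0.42. The calls of the list of ER stress and the integrated stress response (15 of 21 upward, 2 downward, 18 adjusted over the list alone, median 0.59, Asns 1.54 ± 0.05) and of heat shock genes (11 of 13 upward, 1 downward, 12 adjusted over the list alone, median 0.81, Hsp90aa1 1.27 ± 0.05) were lost, at adjusted p = 0.175 and adjusted p = 0.132 with an estimated correlation. Interferon-stimulated genes differed downward in 22 of 25, 22 adjusted over the list alone, including Ddx58 (−1.72 ± 0.27) and Ifit2 (−2.31 ± 0.38), with camera adjusted p = 0.000265 and adjusted p = 0.523 with an estimated correlation. PDGFRb+ stromal identity genes differed downward in 13 of 18 and upward in 3, 16 adjusted over the list alone, with adjusted p = 0.0199 and adjusted p = 0.0756 with an estimated correlation. The ribosomal protein genes differed upward in 28 of 40, by a median of 0.18, but downward in 23 with a median of −0.14 under quantile normalization, and the call (adjusted p = 0.00209) was lost with an estimated correlation (adjusted p = 0.588 with an estimated correlation). Limma called 8765 genes, 4423 upward and 4342 downward, 2190 of them at least 2-fold (923 upward and 1267 downward). The same total in every library moved the median of all genes from −0.02 to −0.28 and gave 2557 upward and 6828 downward calls, 571 and 2051 at 2-fold or more. Under quantile normalization 3927 were upward and 4457 downward, 1009 and 939 at 2-fold or more, and among genes with a mean of at least 100 the latter were 640 and 552. With edgeR on the recovered reads 45.3% of the called genes were upward, against 50.5% in the main test, so the balance of directions rests on the processing.

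**Figure D5:**
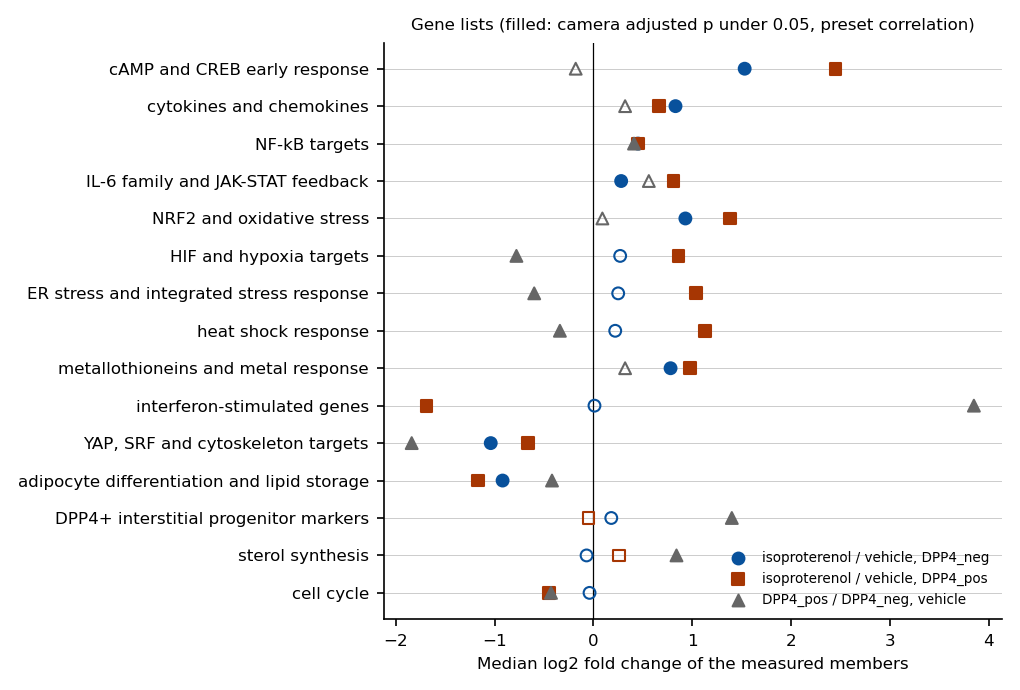
Median log2 difference of the measured members of 15 gene lists for isoproterenol against vehicle in each population and for DPP4_pos against DPP4_neg APCs under vehicle, with filled symbols for camera adjusted p under 0.05 at a preset correlation of 0.01. Interferon-stimulated genes have medians of 3.85 between the populations and −1.69 with isoproterenol in DPP4_pos APCs, and with an estimated correlation neither call is kept.

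Under isoproterenol the populations were compared directly, DPP4_pos against DPP4_neg. DPP4_pos APCs had more Il33 (34.3-fold), Dpp4 (207-fold), the adhesion gene Chl1 (98-fold) and Clec3b (6.56 ± 0.10), and less Aldh1a2 (232-fold), the transcription cofactor gene Eya2 (−6.46 ± 0.12), Myom1 (−5.41 ± 0.17) and the mechanosensitive channel gene Piezo2 (−4.86 ± 0.20). Bmp7 had 7 reads in DPP4_neg and 629 in DPP4_pos libraries, a ratio of 134 (64.6 to 334). Ccl2, not called under vehicle, was higher by 1.38 ± 0.10, while Pdgfrb (−2.10 ± 0.05), Adrb3 (−2.12 ± 0.13), Pparg (−1.59 ± 0.05) and Fabp4 (−1.68 ± 0.08) were lower. Pdgfra stood at 10600 ± 600 normalized counts in DPP4_neg and 10640 ± 438 in DPP4_pos libraries, and Nr4a1 at 4677 ± 270 and 9343 ± 264. Adrb1 was low in both, at 27.8 ± 11.1 and 14.3 ± 6.94.

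DPP4+ progenitor markers were higher in 23 of 25 and lower in 1, 24 adjusted over the list alone, with a median of 1.93 (camera adjusted p = 7.46e-09, and adjusted p = 0.00133 with an estimated correlation). NF-kB targets were higher in 17 of 22 and lower in 2, 19 adjusted over the list alone, with Saa3 at 6.12 ± 0.11 and Sod2 at 1.98 ± 0.04, and IL-6 family and JAK-STAT feedback genes in 17 of 19 and 1, 18 adjusted over the list alone, with Socs3 at 2.04 ± 0.05. Both calls held, with adjusted p = 0.00321 and adjusted p = 0.00218 with an estimated correlation. Cytokine genes were higher in 21 of 28 and lower in 5, 26 adjusted over the list alone, with the chemokine genes Cxcl5 at 5.48 ± 0.12 and Cxcl1 at 4.57 ± 0.11 (camera adjusted p = 0.00132, and adjusted p = 0.0627 with an estimated correlation). HIF targets, lower in DPP4_pos APCs under vehicle, were higher in 12 of 25 and lower in 8, 20 adjusted over the list alone, and were not called (camera adjusted p = 0.693), with a median of 0.02 that was −0.04 under quantile normalization and −0.18 with the same total per library. Metal response genes were higher in 8 of 9, 9 adjusted over the list alone, with Mt2 at 4.36 ± 0.07 (adjusted p = 0.0385 with an estimated correlation). Sterol synthesis genes were higher in 19 of 20 and lower in 1, 20 adjusted over the list alone, with Hmgcs1 at 1.91 ± 0.04 and Insig1 at 1.85 ± 0.03 (camera adjusted p = 1.39e-09, and adjusted p = 0.0701 with an estimated correlation). Cell cycle genes were lower in 36 of 37 and higher in 1, 37 adjusted over the list alone, with a median of −0.77 (camera adjusted p = 4.81e-10, and adjusted p = 0.128 with an estimated correlation). Mural markers were lower in 11 of 14 and higher in 3, 14 adjusted over the list alone (adjusted p = 0.0311 with an estimated correlation), and summed to 78080 ± 2860 and 5695 ± 494 normalized counts in DPP4_neg and DPP4_pos libraries. Endothelial markers were higher in 7 of 10 and lower in 1, 8 adjusted over the list alone, with a median of 1.47 (camera adjusted p = 0.119). The list was called under quantile normalization (adjusted p = 0.0417) and with the same total per library (adjusted p = 0.0316). It summed to 2149 ± 238 and 2337 ± 95.7. Schwann cell markers were higher in 2 of 6 and lower in 3, 5 adjusted over the list alone (camera adjusted p = 0.703). They summed to 1664 ± 79.3 and 2380 ± 207. Limma called 10418 genes, 5237 higher and 5181 lower, 2624 of them at least 2-fold (1206 higher and 1418 lower), and 63.9% of genes had groups that did not overlap. The same total in every library moved the median of all genes from 0 to −0.20, with 3665 higher and 7004 lower, 941 and 1928 at 2-fold or more. Under quantile normalization 4733 were higher and 5419 lower, 1211 and 1181 at 2-fold or more, and among genes with a mean of at least 100 the latter were 746 and 696. With edgeR 47.7% of the called genes were higher, against 50.3% in the main test, so this balance too rests on the processing.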

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

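The tests of the 3 patterns weighed here, on interferon-stimulated genes, contractile genes and the number of genes changed at least 2-fold, were chosen after these results were seen, while the counts over other splits of the libraries were planned.

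In 9 of 124 groups of 4 libraries 1 library stood apart from the others by Dixon's test, where chance alone gives about 1 in 20 groups. Mitochondrially encoded reads made up 1.47% of DPP4_neg isoproterenol replicate 3, against 1.93 to 2.02% in the others of its group. Macrophage and leukocyte markers summed to 1536 normalized counts in DPP4_pos vehicle replicate 1 (659 to 777 in the others). In DPP4_pos vehicle replicate 4, Crem stood at 135 (125 to 126) and Ucp1 at 1.69 (0.743 to 0.896), the latter a difference of single reads. Hmox1, which encodes heme oxygenase, stood at 1881 in DPP4_neg vehicle replicate 4 (1662 to 1693), and Pdgfra at 9704 in DPP4_neg isoproterenol replicate 2 (10790 to 10950). Pdgfrb stood at 2347 in DPP4_pos isoproterenol replicate 1 (1987 to 2044). Epithelial markers summed to 230 in DPP4_neg isoproterenol replicate 1 (55.2 to 70.5), and skeletal muscle markers to 92.1 in DPP4_pos isoproterenol replicate 4 (124 to 129).

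Of 28 genes named for both treatment comparisons, 3 had too few vehicle reads, and of the 25 compared, 21 differed in response by limma's test of the difference. The response was larger in DPP4_pos APCs for 14 and larger in DPP4_neg APCs for 6, and Ccl2 moved in opposite directions (1.52). Differences of the log2 response, DPP4_pos minus DPP4_neg, among genes that rose were 4.09 for Slc7a11, 3.01 for Cxcl1, 2.42 for Nr4a1, 2.06 for Il11, 1.99 for Dio2, 1.87 for Pde4d, 1.07 for Srxn1, 0.80 for Crem, 0.46 for Cd55 and 0.18 for Dgat1. Il33 (−0.64), Pi16 (−1.50) and Ppargc1a (−0.93) rose less in DPP4_pos APCs or did not pass there. Among genes that fell, the differences were −0.77 for Adrb3, −1.32 for Pdgfra, −1.52 for Pdgfrb and −0.72 for Pparg, and, falling less in DPP4_pos APCs, 1.30 for Ctgf, 0.56 for Dpp4 and 0.32 for Vcl. Of the lists, 16 differed by camera at the preset correlation and 5 of these also with an estimated one, namely the cAMP, IL-6 and JAK-STAT, NF-kB, HIF and metal response lists. The cAMP, IL-6 and JAK-STAT, and NF-kB lists share members, so these calls are not independent. The median differences were 0.80 for the cAMP response, 0.78 for IL-6 and JAK-STAT feedback, 0.59 for NF-kB targets, 0.81 for HIF targets, 0.81 for heat shock, 0.59 for the integrated stress response, 0.36 for metal response genes, 0.46 for sterol synthesis, 0.51 for BMP targets, 0.55 for YAP and SRF targets, −0.32 for cell cycle, −0.38 for PDGFRb+ identity, −1.80 for interferon-stimulated genes and −1.02 for Schwann markers. The medians of 0.25 for NRF2 targets and 0.18 for ribosomal proteins turned to −0.02 and −0.08 with the same total per library. Under that scaling the medians also moved to 0.10 for metal response genes, 0.20 for sterol synthesis, 0.25 for BMP targets, 0.30 for YAP and SRF targets, 0.33 for NF-kB targets, 0.33 for the integrated stress response, 0.51 for IL-6 and JAK-STAT feedback, −0.58 for cell cycle and −0.64 for PDGFRb+ identity. Among the calls that were lost, sterol synthesis had adjusted p = 0.311, BMP targets adjusted p = 0.132, YAP and SRF targets adjusted p = 0.32, cell cycle adjusted p = 0.401, Schwann markers adjusted p = 0.132 and NRF2 targets adjusted p = 0.575 with an estimated correlation. Under quantile normalization NRF2 targets (adjusted p = 0.339), sterol synthesis (adjusted p = 0.0518) and Schwann markers (adjusted p = 0.124) were not called either, nor were Schwann markers (adjusted p = 0.101) and ribosomal proteins (adjusted p = 0.941) with the same total per library.

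Interferon-stimulated genes had a median log2 difference of 3.85 between DPP4_pos and DPP4_neg vehicle libraries. The sum of the 23 macrophage and leukocyte markers, tested or not, rose by 0.765% of the rise of the interferon list, which argues against RNA of such cells as the source. Of the 15 measured, none is in another list and 10 had a mean of at least 10 normalized counts in every group. Their median log2 difference was 0.47 (camera adjusted p = 0.663). Single genes, named after their values were seen, went both ways. The abundant macrophage gene Lyz2 stood at 306.7 ± 121 against 277 ± 160 normalized counts. Mrc1 (151 ± 160 against 26.16 ± 21.4) and Adgre1 (40.66 ± 12.5 against 25.9 ± 17.3) were higher on average, and Cd74 and Tyrobp lower. A PDGFRb sort should remove those cells, though reads of these genes remained in every group. DPP4_pos vehicle replicate 1 was the highest of its group in both lists (46020 and 1536), while replicate 3, second in interferon genes (30440), was the lowest in leukocyte markers (659). With each of the 8 vehicle libraries left out singly the median was 3.63 to 4.11, lowest without DPP4_pos vehicle replicate 1. The lowest sum of a DPP4_pos vehicle library (18200) was above the highest of a DPP4_neg one (6206). These values argue against a single library as the whole cause. Under the other scalings the list median was at least 3.9. They moved the median of all genes only from −0.01 to 0.05 (same total per library) and −0.03 (quantile normalization). They could hardly have removed a difference of this size, so nothing further is concluded from them. A standing interferon response in cultured DPP4_pos APCs is a candidate explanation, found and tested on the same data, and a difference in how the cultures were handled was not tested.

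Contractile genes were higher in DPP4_neg than in DPP4_pos vehicle libraries, with a median for YAP and SRF targets of −1.84. That median stayed at −1.77 or lower under the other scalings. They moved the median of all genes only from −0.01 to 0.05 (same total per library) and −0.03 (quantile normalization). A list median of this size could hardly have turned under them, so the test shows only that it does not rest on the choice among these scalings. Smooth muscle cells or pericytes in the DPP4_neg cultures, which a PDGFRb sort could keep, cannot be told apart from contractile gene expression by the progenitors themselves. The mural markers that are not contractile proteins had a median of −1.35, with 6 of 10 lower in DPP4_pos libraries, 1 higher and 3 not called. Mcam, Abcc9 and Rgs4 were lower in DPP4_pos libraries while Notch3 was higher and Rgs5 (−0.48), Kcnj8 (0.41) and Cspg4 (−0.38) were not called, all named after their values were seen except Abcc9. Cspg4 was called under 6 other settings, from −0.36 to −0.50, Rgs5 under quantile normalization (−0.76), and Kcnj8 without DPP4_neg vehicle replicate 2 (0.52), without DPP4_pos vehicle replicate 1 (0.63) or without the 2 libraries high in interferon genes (0.63). Of the 14 mural markers measured, 3 are in another list and 11 had a mean of at least 10 normalized counts in every group.

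Isoproterenol changed 2.01 times as many genes at least 2-fold in DPP4_pos as in DPP4_neg APCs. The ratio was 2 with reads thinned to the shallowest library, 2.2 among genes with a mean of at least 100 and at lowest 1.83 under other scalings. These values argue against depth, noise of low genes and the authors' scaling as the whole cause. A stronger response of DPP4_pos APCs may account for it, as a hypothesis from the same data, and a difference in the dose or time that each culture received was not tested.

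Other splits of the libraries were counted for each comparison, 35 splits of 8 libraries or, for the difference of responses, 100 drawn splits, with lists adjusted within each comparison. For isoproterenol in DPP4_neg APCs 1 of 35 splits, the real one, gave 9199 genes, 2137 genes at 2-fold and 10 lists, where the highest of the others gave 0, 0 and 9. In DPP4_pos APCs 1 of 35 gave 11581, 4295 and 18, where others reached 0, 0 and 17, and under vehicle 1 of 35 gave 9326, 2216 and 17, where others reached 0, 0 and 15. Under isoproterenol 1 of 35 gave 10418 genes and 2624 at 2-fold, where others reached 1 and 1. Mixing libraries of groups that differ in so many genes widens the spread within each group, so the other splits could hardly call genes. Their low counts of genes were thus nearly fixed in advance and give no support of their own to the real grouping. The counts of genes also cannot exclude chance differences between cultures or animals, since the replicates may be technical. The list counts of the first 3 comparisons were the highest of 35 splits, but by 1 or 2 lists, so splits with mixed labels gave nearly as many. For the 17 lists called under isoproterenol chance is not excluded, since 9 of 35 splits gave as many and others reached 20. For the difference of responses 1 of 100 splits gave at least 8765 genes, 3 at least 2190 at 2-fold and 2 at least 16 lists, where others reached 8411, 3723 and 16. Splits that mix the treatment also break the responses themselves. They therefore do not test whether the responses of the populations are equal, and chance was not decided for this comparison. The splits that reached the 8411 genes, 3723 at 2-fold and 16 lists kept or reversed the treatment of all DPP4_pos libraries and mixed it among DPP4_neg ones. Of 96 splits that mixed the treatment in both populations, none called a gene, but 8 called 15 lists.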

How the results depend on the processing

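The thinned reads, the counts at 2-fold under other settings, and the fits without the 2 libraries high in interferon genes, the 2 with keratin reads or the 3 highest in macrophage markers were chosen after seeing the data. Requiring a 2-fold change by construction lowered the counts of called genes to 2137 and 4295 for isoproterenol in DPP4_neg and DPP4_pos APCs, 2190 for the difference of responses, and 2216 and 2624 between populations under vehicle and isoproterenol. With a mean of at least 100, which tests fewer genes, the counts at 2-fold were 1133, 2496, 1192, 1176 and 1442 in that order. All other settings kept the counts within 1.5 times. The balance of all called genes turned for isoproterenol in DPP4_neg APCs under quantile normalization (4789 up, 4352 down) and with a mean of at least 100 (3902 and 3569), in DPP4_pos APCs with a mean of at least 100 (4814 and 4167), and between populations under vehicle with the same total per library (5151 higher, 4241 lower). DESeq2 on the recovered reads called 9175, 11354, 8408, 9478 and 9965 genes, and edgeR 9543, 11581, 8773, 9833 and 10242. Leaving out single libraries gave 8707 to 9021, 11298 to 11442, 8420 to 8699, 8838 to 8984 and 10150 to 10319 genes, and 2096 to 2184, 4277 to 4329, 2122 to 2237, 2174 to 2238 and 2626 to 2666 at 2-fold. The correlation of the responses was 0.747 to 0.758 without single libraries, and 0.746 with a pseudocount of 8, beyond the jackknife SE of 0.0092. Of 79 list calls at the preset correlation, 21 calls were made with an estimated correlation, 81 under quantile normalization (71 of the 79 kept and 1, ribosomal proteins in the difference of responses, reversed) and 77 with the same total per library (73 kept). The list tests were not repeated without single libraries. Adrb1 in DPP4_neg APCs turned from 0.20 to −0.02 without DPP4_neg isoproterenol replicate 1 and to −0.04 without the 2 libraries with keratin reads, of a range from −0.02 to 0.39 over single libraries left out, and Ppargc1a in DPP4_pos APCs to −0.06 with the same total per library. Lyz2 between populations under vehicle turned from 0.23 to −0.02 without DPP4_neg vehicle replicate 1, to −0.01 without DPP4_pos vehicle replicate 1 and to −0.01 without the 2 libraries high in interferon genes, of a range from −0.02 to 0.58 over single libraries left out. None of these values was called before or after, and the cause was not tested. Over the named genes, 3260 values under alternative settings and 2009 without a single library kept direction and side of the threshold, while 7 and 1 lost their call and 13 and 3 gained one. A fit to the compared groups alone cannot be made for the difference of responses, which needs all 4. Replicate numbers were not taken to pair the libraries, since the labels name no pairing. Of 24 pairs with the same number 8 had a correlation of deviations over 0.1 (median 0.0535, from −0.264 to 0.265), while 10 of 72 pairs with different numbers did (median −0.0315). Of 16 libraries, 9 correlated best with their own number. These values lean toward some pairing by number, which was not settled. The replicate block gave 9168, 11561, 8854, 9393 and 10451 genes and 76 list calls, all 76 among the 79, without NF-kB targets and IL-6 family genes in DPP4_neg APCs and NRF2 targets in the difference of responses. Depth limits the folds of genes with few vehicle reads, such as Ucp1, Ren1 and Ramp3, to their counting intervals.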

Other observations

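The hypotheses on progenitor markers and gene span were written before their results were seen, and the genes of the lists described first were chosen by adjusted p.

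Further groups moved with isoproterenol in DPP4_pos APCs. Cell cycle genes fell in 28 of 37 and rose in 7, 35 adjusted over the list alone, with thymidine kinase Tk1 at −1.67 ± 0.08 and the replication clamp Pcna up by 1.31 ± 0.04 (camera adjusted p = 0.0053, and adjusted p = 0.467 with an estimated correlation). Wnt pathway genes fell in 16 of 26 and rose in 7, 23 adjusted over the list alone, with Wisp2 at −2.80 ± 0.04 and the Wnt enhancer Rspo2 at −4.57 ± 0.14 (camera adjusted p = 0.0234, adjusted p = 0.132 with an estimated correlation and adjusted p = 0.112 with the same total per library). Committed preadipocyte markers fell in 14 of 22 and rose in 5, 19 adjusted over the list alone, including Cebpa (−1.79 ± 0.05) and the amine oxidase Aoc3 (−1.96 ± 0.04), with camera adjusted p = 0.0324 and adjusted p = 0.454 with an estimated correlation. Extracellular matrix genes fell in 21 of 33 and rose in 7, 28 adjusted over the list alone, with the lysyl oxidase Loxl2 up by 1.56 ± 0.04 (camera adjusted p = 0.0344, and adjusted p = 0.307 with an estimated correlation). Schwann cell markers fell in 6 of 6, 6 adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.111 with an estimated correlation and adjusted p = 0.055 with the same total per library), and summed to 5235 ± 177 normalized counts under vehicle and 2380 ± 207 under isoproterenol. Other lists were not called. Clock genes rose in 9 of 18 and fell in 9, 18 adjusted over the list alone, with Arntl up by 2.93 ± 0.04, Nfil3 up by 2.10 ± 0.04 and Per3 at −3.06 ± 0.07 (camera adjusted p = 0.663, median 0.19 and mean −0.02, and a median of −0.01 under quantile normalization). BMP targets rose in 10 of 22 and fell in 10, 20 adjusted over the list alone, with Inhba up by 3.82 ± 0.10 and Bambi by 3.11 ± 0.10 (camera adjusted p = 0.995, median −0.16 and mean 0.14). In DPP4_neg APCs the BMP targets fell in 14 of 22 and rose in 5, 19 adjusted over the list alone, with a median of −0.69 (camera adjusted p = 0.00978, and adjusted p = 0.0963 with an estimated correlation). Growth factors in DPP4_pos APCs rose in 11 of 30 and fell in 13, 24 adjusted over the list alone, with Vegfa up by 2.20 ± 0.04 and Vegfd at −2.39 ± 0.05 (camera adjusted p = 0.916, median −0.18, mean 0.17, and a median of 0.30 under quantile normalization).

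In DPP4_pos APCs p53 targets rose in 12 of 21 and fell in 7, 19 adjusted over the list alone, with Plk3 up by 2.27 ± 0.08 and Sesn1 at −1.83 ± 0.06 (camera adjusted p = 0.645). In DPP4_neg APCs p53 targets fell in 14 of 21 and rose in 4, 18 adjusted over the list alone (camera adjusted p = 0.0324, and adjusted p = 0.259 with an estimated correlation), and committed preadipocyte markers fell in 15 of 22 and rose in 4, 19 adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.418 with an estimated correlation). Glucocorticoid targets in DPP4_pos APCs rose in 7 of 14 and fell in 5, 12 adjusted over the list alone, with Errfi1 up by 4.00 ± 0.03 and Pdk4 at −4.25 ± 0.10 (camera adjusted p = 0.448, and a median of 0.23 that was −0.05 with the same total per library). CD142+ progenitor markers fell in 9 of 15 and rose in 4, 13 adjusted over the list alone, with Cygb at −2.20 ± 0.04 and F3, which encodes CD142, at −1.79 ± 0.05 (camera adjusted p = 0.33). Lipolysis genes fell in 11 of 17 and rose in 6, 17 adjusted over the list alone, with the lipase cofactor Abhd5 up by 2.25 ± 0.04 (camera adjusted p = 0.33). Matrix proteases rose in 11 of 21 and fell in 9, 20 adjusted over the list alone, with Adamts4 up by 4.48 ± 0.05 and Adamts9 by 3.84 ± 0.04 (camera adjusted p = 0.788, and a median of 0.11 that was −0.18 under quantile normalization). Sterol synthesis genes rose in 11 of 20 and fell in 6, 17 adjusted over the list alone (camera adjusted p = 0.11, and a median of 0.26 that was −0.01 with the same total per library). Mitochondrially encoded genes rose in 9 of 12, 9 adjusted over the list alone (camera adjusted p = 0.109). The list holds COX2, COX3 and ATP6, which had means of 56.9, 14.4 and 11.7 normalized counts over all libraries where COX1 had 103100. Both under quantile normalization and with the same total per library 5 rose, and the median went from 0.43 to 0.25 and 0.15. Endothelial markers rose in 3 of 10 and fell in 4, 7 adjusted over the list alone, with the VEGF receptor Kdr up by 4.08 ± 0.13 (camera adjusted p = 0.988, and a median of 0.03 that was −0.23 with the same total per library and 0.53 under quantile normalization). Mural markers fell in 8 of 14 and rose in 4, 12 adjusted over the list alone (camera adjusted p = 0.396). Macrophage and leukocyte markers rose in 2 of 15, 4 under quantile normalization and 2 adjusted over the list alone, including the receptor Csf1r (0.77 ± 0.11), with camera adjusted p = 0.619. Of 2 mesothelial markers 1 rose and 1 fell, of 2 epithelial ones 1 fell, and all 3 skeletal muscle markers fell, lists too small to test.

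Some lists called between the populations were also without a call at an estimated correlation. Under vehicle, cell cycle genes were lower in DPP4_pos APCs in 29 of 37 and higher in 1, 31 adjusted over the list alone (adjusted p = 0.259 with an estimated correlation), p53 targets lower in 16 of 21 and higher in 3, 19 adjusted over the list alone (adjusted p = 0.132 with an estimated correlation), and heat shock genes lower in 8 of 13 and higher in 1, 9 adjusted over the list alone (adjusted p = 0.424 with an estimated correlation and 0.0676 under quantile normalization). Extracellular matrix genes were lower in 19 of 33 and higher in 10, 29 adjusted over the list alone (adjusted p = 0.253 with an estimated correlation and 0.175 under quantile normalization), and PDGFRb+ identity genes higher in 9 of 18 and lower in 4, 13 adjusted over the list alone (adjusted p = 0.123 with an estimated correlation and 0.0525 with the same total per library). Under isoproterenol, interferon-stimulated genes were higher in 21 of 25 and lower in 1, 22 adjusted over the list alone (adjusted p = 0.645 with an estimated correlation), NRF2 targets higher in 15 of 22 and lower in 4, 19 adjusted over the list alone (adjusted p = 0.339 with an estimated correlation), heat shock genes higher in 11 of 13 and lower in 2, 13 adjusted over the list alone (adjusted p = 0.296 with an estimated correlation), and matrix proteases higher in 16 of 21 and lower in 3, 19 adjusted over the list alone (adjusted p = 0.0511 with an estimated correlation). Adipocyte genes were lower in 18 of 28 and higher in 5, 23 adjusted over the list alone (adjusted p = 0.2 with an estimated correlation), YAP and SRF targets lower in 18 of 26 and higher in 7, 25 adjusted over the list alone (adjusted p = 0.227 with an estimated correlation), extracellular matrix genes lower in 20 of 33 and higher in 10, 30 adjusted over the list alone (adjusted p = 0.175 with an estimated correlation), and ribosomal protein genes lower in 37 of 40, 37 adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). The cAMP response, higher in 27 of 31 and lower in 4, 31 adjusted over the list alone, kept its call (adjusted p = 0.0421 with an estimated correlation).

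Whether isoproterenol moves DPP4_neg APCs toward the DPP4_pos vehicle profile was tested by correlating, across genes, the response of DPP4_neg APCs with the vehicle difference between the populations. Both share the DPP4_neg vehicle libraries, and with these shared r was 0.204 and the covariance 0.179. Simulated groups of noise alone, with the same libraries shared, gave r = 0.5 and a covariance of 0.015 over 100 simulations. That r follows from the shared libraries where nothing else differs, so it is no reference level for r in these data. With the control libraries split so that none was shared, the median over 6 splits was r = 0.192 (0.163 to 0.218), the covariance 0.17 and Spearman's rho 0.083. With the same split controls, a median of 239 genes higher in DPP4_pos APCs by at least 2-fold rose at least 2-fold with isoproterenol, where independent lists would share 74.4, and 388.5 lower ones fell, where they would share 84.9. Genes moving away were also above independence, with 165 higher ones that fell (105.9) and 89 lower ones that rose (60.4). The split of the counts was added after the unsplit counts were seen. The values are in the direction of a weak shift toward the DPP4_pos profile, but the DPP4+ progenitor markers as a list were not called in DPP4_neg APCs, with 13 of 25 up, 10 down and a median of 0.18 (camera adjusted p = 0.446), and Dpp4 itself fell. Dpp4, used in the sort, had only 5 to 12 reads per DPP4_neg isoproterenol library. It also fell in DPP4_pos APCs (−0.46), where the list was mixed too, with 11 up and 10 down. The fall of Dpp4 therefore says little about such a shift.

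Longer genes could have fallen more within 4 h, since their transcripts take longer to renew. Gene span, known for 13730 tested genes (98%), correlated across genes with the fold change at rho = −0.021 in DPP4_pos and −0.105 in DPP4_neg APCs, against 0.088 for the vehicle difference between populations. Genes that fell at least 2-fold had a median span of 33.2 kb in DPP4_neg and 24.1 kb in DPP4_pos APCs, those that rose 26.3 and 24.3 kb, and all genes 23.1 kb. These values left the hypothesis undecided.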
